A study of Mus musculus with 4 samples.

How the data were processed

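The data were 4 RNA-seq libraries of mouse pachytene spermatocytes, 2 from wild-type and 2 from homozygous Ddx4 knock-in mice. Per the labels' protocols, testes were digested in steps, first with collagenase against Leydig cells and then with trypsin, germ cells were separated by centrifugal elutriation with purity judged by DAPI staining, and libraries were made from total RNA with a kit that does not mark strand. Reads of overlapping and antisense genes can therefore not be told apart. The submitters' processing notes name Bowtie and the builds mm10 and GRCm38; the quantifier and the annotation release are not given in the sources used here. Per the file headers, the authors deposited expected counts, TPM, lengths and effective lengths for 55364 genes, and expected counts, TPM and the percent of each gene's transcripts held by each isoform. The deposited expected counts are estimates and not all whole numbers. The TPM values deposited by the authors are scaled to the same total per library after division by effective length. The isoform percent values were used as deposited by the authors.

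Gene models were taken from a reference annotation of GRCm38, the build in the submitters' notes, in which 55104 of the 55364 gene identifiers were found; the table held 0 mitochondrial genes. Expected counts were rounded to whole numbers. The main test was edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter, a quasi-likelihood fit on genotype and Benjamini-Hochberg adjustment at 0.05. It left 16571 genes. Standard errors were the log2 fold change divided by the square root of F. CPM values are on the TMM scale. Gene lists were tested with limma 3.58.1, by camera with a preset correlation of 0.01 and with an estimated correlation, and by fry, over 26 lists with at least 3 tested genes. With an estimated correlation, camera judges its statistic on the 2 residual degrees of freedom, so a call lost there need not reflect correlation between genes. Isoforms with at least 10 counts in at least 2 libraries were tested with edgeR's diffSpliceDGE and Simes p-values per gene. Where a ratio of counts is given with an interval, it is an exact 95% interval, and a gene without counts in one genotype is given as a bound against a floor of 3 counts over the group; both cover counting error only.

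The tests were tried on simulated counts drawn with the means, library sizes and dispersions of these data. Over 6 simulated data sets with 200 changed genes each among 16571, the gene test recovered 36.3% of genes changed 1.25-fold, 66.0% at 1.5-fold, 79.7% at 2-fold and 96.0% at 4-fold, and 8.85% of its calls were unchanged genes. The changed genes had a mean of at least 1 CPM and moved in random directions. In the data 7237 genes passed, with unequal directions at 2-fold, so these rates need not hold there. In 10 simulated data sets, each with 1 list of 40 genes shifted by 0.4 (log2), camera called the shifted list in 10 with the preset and in 6 with an estimated correlation, and fry in 7. Of 250 unchanged lists camera called 0 and fry 1; the simulated genes were independent, so correlation within lists was not covered. The planned isoform test failed this check: over 3 simulated data sets with 200 genes changed 2-fold each, it recovered 10.0% of them, and 83.2% of its calls were unchanged genes. With a low constant dispersion the same code made 5.3% such calls, so the false calls arose at the dispersion of these isoforms, which had a median coefficient of variation of 38.0% with 2 residual degrees of freedom. The test was kept because it had been fixed before the data were examined, and it is reported with limma's diffSplice beside it. A quasi-likelihood fit, added after this was seen, recovered 3.17% with 78.2% of calls unchanged and did not repair it.

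The groups, tests, gene lists, settings to be varied and the rule for named genes were fixed before the data were examined. The rule took Ddx4, the 12 genes with the largest change in each direction among those past the test with a mean of at least 1 CPM and no overlap between genotypes, up to 2 risers and 2 fallers of each list, and the 5 genes with the smallest isoform p. Not every gene this rule took is reported here. Provisional gene symbols were left out of the ranking (7 above the 12th riser and 7 above the 12th faller). The settings varied were other scaling factors, DESeq2 1.42.0, limma on log2(TPM + 1), other expression filters, a replicate block, offsets for effective length and for a length trend, limma's diffSplice and a minimum of 30 counts for isoforms, and each library left out in turn. The trend offsets were centred per library to keep the TMM scale, a correction made after a first run without it had been seen. After the results were seen, each list was also set against 10000 autosomal lists of the same size matched on mean CPM, drawn from windows of 200 genes.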

Results

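RNA sequencing was used to compare pachytene spermatocytes, the germ cells in mid-prophase of the first meiotic division, from wild-type mice (WT) and from mice homozygous for a knock-in at Ddx4 (KK). Ddx4 encodes the germline RNA helicase also called mouse vasa homolog, a core protein of germ granules. The series title places the comparison in the question of how germ granules that form by phase separation bear on RNA homeostasis and germline development. The cells were enriched from testis by centrifugal elutriation, and each genotype had 2 libraries. The total expected count was 18156099 and 19246124 in the WT libraries and 19438570 and 17970207 in the KK libraries. Pearson's r of log2 CPM across genes was 0.989 between the WT libraries, 0.990 between the KK libraries and 0.973 to 0.974 between genotypes; genes are not independent replicates. Nothing in the labels says that the libraries of a genotype came from separate animals. The p-values of single genes and isoforms therefore rest on the spread between these samples, which may be technical. Camera p-values set a list against the other genes, and permutation p-values rest on genes.

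The Ddx4 transcript itself was 5.05-fold lower in the KK libraries. Ddx4 (chromosome 13, 112598333 to 112652475, minus strand, GRCm38) stood at 264.96 and 272.92 TPM in the WT libraries and at 54.44 and 52.49 TPM in the KK libraries. In normalised counts it was 556 ± 11.9 CPM in WT and 110 ± 3.06 CPM in KK (mean ± SD, n = 2 each). The log2 fold change of Ddx4 was -2.34 ± 0.04 (SE), with an edgeR quasi-likelihood adjusted p of 6.8e-27. Both annotated coding isoforms were lower: Ddx4-202 had 7567 and 8403 counts in WT against 1650 and 1438 in KK, and Ddx4-201 had 2081 and 2148 against 605 and 546. The counts hold only reads that match the reference gene model, and the sequence inserted at the locus was not analysed here.

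**Figure D1:**
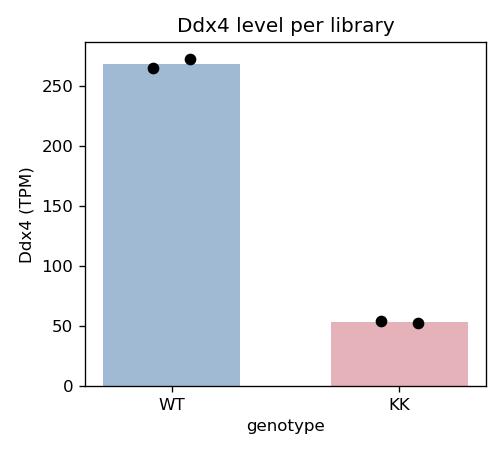
Ddx4 level in TPM (vertical axis) in each genotype (horizontal axis). Bars give the mean of 2 libraries and points the single libraries; the KK libraries, at 54.44 and 52.49 TPM, lie below the WT libraries, at 264.96 and 272.92 TPM.

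The knock-in was accompanied by differences across much of the transcriptome, most of them small. Of 16571 genes tested, 7237 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 3648 higher and 3589 lower in KK. Among those that changed at least 2-fold the directions were unequal, with 1471 genes higher and 125 lower. The antigen-presentation chaperone homolog Tapbpl rose from 0.794 ± 0.24 to 17.0 ± 2.14 CPM (21.1-fold), and Ltc4s, which encodes leukotriene C4 synthase, had 5 WT and 130 KK counts (ratio 24.5, 95% counting interval 10.2 to 76.8). Angptl2 (11.2-fold), Slco2b1 (11.7-fold), Psd4 (11.4-fold), Spdef (11.2-fold), Rtn4rl1 (10.9-fold), Trh (10.8-fold), Sel1l3 (10.7-fold) and Asprv1 (10.7-fold) also rose, each from under 1 CPM in WT, so these folds are loosely bounded: the counting interval of the ratio was 5.58 to 27.2 for Spdef, 5.46 to 26.7 for Trh and 6.01 to 21.5 for Asprv1, which rose 20.2-fold without WT replicate 2. The X-linked Btbd35f28 and Btbd35f4 belong to a family of near-identical copies, so their reads are assigned with uncertainty. Btbd35f28 had 2 WT counts and 115 KK counts, a ratio of 54.2 with a 95% counting interval of 14.7 to 453, and rose 26.3-fold without WT replicate 1. Btbd35f4 had 6 WT and 136 KK counts, a ratio of 21.4 with an interval of 9.57 to 59.3, and rose 30.9-fold without WT replicate 1.

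After Ddx4, the fallers taken by the rule for named genes were Serpinc1 (3.37-fold lower), Btnl10 (3.24-fold), Six4 (3.20-fold), Rnf165 (3.15-fold), Igip (2.79-fold), Pmp2 (2.60-fold), Fndc5, Sytl4, Gimap1os and Dhh, each from under 5 CPM in WT. The last 4 lost their call in 3, 5, 5 and 5 alternatives, and their count ratios of KK to WT had 95% intervals of 0.257 to 0.568, 0.235 to 0.666, 0.272 to 0.620 and 0.270 to 0.631. Fndc5 was 4.66-fold lower without KK replicate 2 and Gimap1os 4.16-fold lower without KK replicate 1. Outside the rule, the provisional genes A530084C06Rik and Gm42791, singled out after their values were seen, had 0 KK counts and were at least 12.7-fold and at least 10.9-fold lower against a floor of 3 counts over the KK group. Kmt2d, a histone H3 lysine methyltransferase gene, was the abundant member of this group and fell from 79.5 ± 4.0 to 31.6 ± 0.44 CPM (2.52-fold, adjusted p of 1.8e-14 by edgeR). The number of changed genes depended on the test: DESeq2 called 4564, limma on log2 TPM 3408 and edgeR with an effective length offset 4662. With library size scaling in place of TMM, 64.2% of the calls were higher in KK, against 50.4% with TMM.

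**Figure D2:**
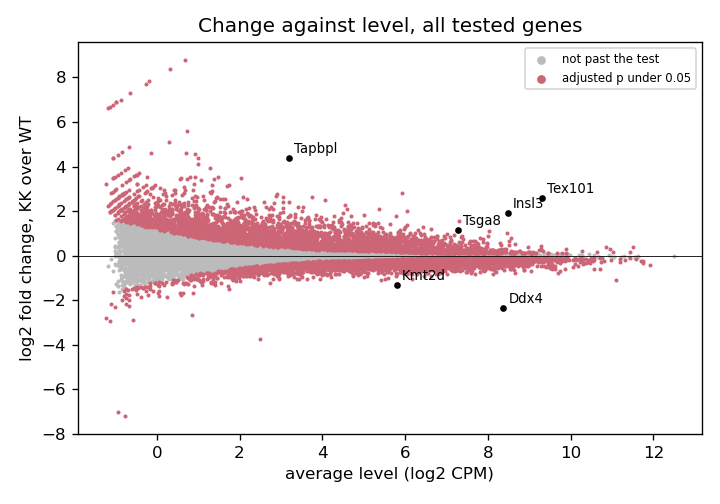
Log2 fold change of KK over WT (vertical axis) against average level in log2 CPM (horizontal axis) for the 16571 tested genes; red points passed an adjusted p of 0.05 and 6 genes are named. Rises of at least 2-fold (1471 genes) outnumber falls (125 genes); fitted values of genes without counts in one genotype depend on the prior count.

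Genes of both sex chromosomes were higher in KK as a group. Of 568 tested X-linked genes 327 rose and 6 fell (335 and 8 adjusted over the list alone), with a median log2 fold change of 0.89, and of 102 tested Y-linked genes 68 rose and 0 fell (76 rose adjusted over the list alone), with a median of 1.38. The autosomal medians lay between -0.05 and 0.07. The Y-linked genes stood at low levels, with a median of 0.556 CPM in WT and 1.68 CPM in KK. Y-linked genes too low in WT to pass the expression filter there, with or without WT counts, passed it through the KK libraries alone. This favours rises, and how many genes entered in this way was not counted. The X chromosome took 0.266% ± 0.001 of the counts in WT and 0.430% ± 0.003 in KK (mean ± SD, n = 2 each), and the Y chromosome 0.0128% ± 0.0001 and 0.0313% ± 0.0006. Widely expressed X-linked genes took part, among them Ube2a, a ubiquitin-conjugating enzyme gene (3.44 to 8.04 CPM), and the ribosomal protein gene Rpl10 (6.75 to 14.8 CPM). The Y-linked zinc finger gene Zfy2 rose from 1.92 to 6.22 CPM and the Y-linked translation factor gene Eif2s3y from 8.63 to 17.9 CPM. The X-linked Stk26 and Sytl4 went the other way. Stk26 had 31 WT and 8 KK counts, a ratio of 0.243 with a 95% interval of 0.0967 to 0.541 (7.51-fold lower without KK replicate 1), and its call was lost in 3 alternatives. Gm20813 and Gm20924 on the Y chromosome, also members of a multicopy family, had 0 WT counts and were at least 35.5-fold and at least 26.7-fold higher against a floor of 3 counts over the WT group. The bounds of all 4 Y-linked genes without WT counts lay above the list median of 1.38, so putting them at their bound could not change it. This does not address other Y-linked genes that passed the filter through the KK libraries alone. The camera adjusted p was 3.6e-14 for the X list and 6.1e-09 for the Y list with a preset correlation. Neither list passed with an estimated correlation (adjusted p = 0.147 for both). The estimates, 0.003 for X and -0.002 for Y, lay below the preset 0.01, so correlation within these lists does not account for the lost calls. DESeq2 called 193 X-linked and 29 Y-linked genes higher, limma on log2 TPM 176 and 43.

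**Figure D3:**
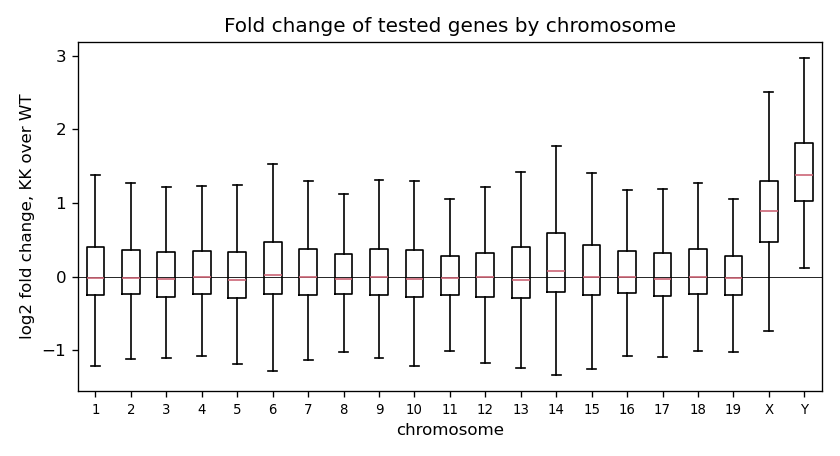
Log2 fold change of KK over WT (vertical axis) of the tested genes on each chromosome (horizontal axis); boxes give the median and interquartile range and whiskers reach 1.5 times that range, with points beyond it left out. The X and Y medians, 0.89 and 1.38, lie above all autosomal medians, which run from -0.05 to 0.07.

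Transcripts of germ granule proteins were lower in KK as a list, by an amount within that of autosomal genes of like abundance. Of 32 tested members 17 fell and 5 rose (17 and 7 adjusted over the list alone), with a median log2 fold change of -0.18. The central 95% of medians of 10000 autosomal lists matched on CPM ran from -0.19 to -0.003, and in those lists 28.1% to 59.4% of genes fell, against 53.1% in this list. Tdrd5, a tudor domain protein gene of the piRNA pathway, fell from 297 ± 1.8 to 192 ± 0.66 CPM, while Dazl, a germ cell RNA-binding protein gene, rose from 50.1 to 64.2 CPM and Kif17 rose from 150 to 179 CPM. Of 55 RNA decay and P-body genes 29 fell and 7 rose (31 and 7 adjusted over the list alone), and their median of -0.22 lay below the range of matched lists (-0.16 to 0.01). Upf1, the helicase of nonsense-mediated decay, fell from 261 ± 5.4 to 149 ± 4.6 CPM and Ddx6, a P-body helicase gene, from 90.0 to 56.9 CPM, whereas Tnrc6b, a partner of Argonaute proteins, rose from 9.25 to 35.3 CPM. The camera adjusted p was 2.4e-07 for germ granule and 6.3e-04 for RNA decay genes; neither passed with an estimated correlation (adjusted p = 0.269 for both). The germ granule list holds Ddx4 itself, and without it the adjusted p was 0.00108 with the preset and the adjusted p = 0.36 with an estimated correlation.

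Among spermatocyte genes, 14 of 28 pachytene markers fell and 3 rose, the same counts adjusted over the list alone. Piwil1, the pachytene PIWI protein gene, fell from 942 ± 2.5 to 629 ± 21.5 CPM, and Mybl1, a transcription factor gene of pachytene, from 118 to 75.5 CPM, while Spag6 rose from 40.9 to 72.0 CPM. The pachytene median of -0.10 lay within the range of matched lists (-0.18 to -0.01). The pachytene list passed camera (adjusted p of 0.0053) but not with an estimated correlation (adjusted p = 0.269). Of 48 meiotic prophase genes 11 rose and 17 fell (11 and 18 adjusted over the list alone). Tex101, a germ cell surface protein gene in this list, rose from 181 ± 0.02 to 1083 ± 2.2 CPM (5.98-fold), and the recombinase gene Dmc1 rose 2.20-fold, while Terb1 fell 1.44-fold. The median of this list (-0.11) and its mean (0.06) differed in sign, and it did not pass camera (adjusted p of 0.614). Of 31 meiotic division genes 2 rose and 10 fell, the same counts adjusted over the list alone, among them Espl1, the separase gene (236 to 172 CPM), and the list missed the camera threshold (adjusted p of 0.135) but passed fry, which does not compare it with other genes (adjusted p of 0.0127). Of 31 genes of the sex chromosome silencing and DNA damage response list 3 rose and 13 fell, the same counts adjusted over the list alone. The risers Zfy2 and Ube2a are themselves sex-linked, and the camera adjusted p was 0.054. This list did not pass camera with an estimated correlation (adjusted p = 0.332), a length trend offset (0.201) or a mean CPM of at least 1 (0.095). Nor did it pass with TMM factors from autosomal genes (0.059), a GC trend offset (0.055) or RLE scaling factors (0.053). It passed with a replicate block (0.047) and under fry (0.037), and its camera call varied with the library left out. Its median of -0.16 lay within the range of matched lists (-0.19 to 0.08).

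Markers of other testis cells differed between the genotypes. Leydig cell markers were higher, with 12 of 18 risen and 0 fallen, and the hormone gene Insl3 rose from 149 ± 6.5 to 564 ± 9.8 CPM (3.77-fold). Spermatogonial markers were also higher, with 12 of 28 risen and 2 fallen; Zbtb16 (10 WT and 56 KK counts) and Lin28a (10 and 55) rose, with count ratios of 5.28 (95% interval 2.67 to 11.6) and 5.19 (2.62 to 11.4), while Id4 fell from 93.4 to 70.1 CPM. Zbtb16 was 3.17-fold higher without KK replicate 2 and 8.78-fold without WT replicate 1, and Lin28a 8.14-fold higher without WT replicate 2. Both counts were unchanged when adjusted over the list alone. The camera adjusted p was 3.3e-11 for Leydig and 0.0099 for spermatogonial markers, with an adjusted p = 0.147 and an adjusted p = 0.280 with an estimated correlation. Of 22 Sertoli cell markers 4 rose and 6 fell, including Ptgds, which rose from 26.7 to 71.9 CPM, and Dhh, which fell. Of 16 peritubular and endothelial markers 9 rose and 1 fell, and of 10 macrophage and immune markers 4 rose and 0 fell; Csf1r had 2 WT and 27 KK counts, a ratio of 12.7 with a 95% counting interval of 3.20 to 110. Of 58 spermatid genes 24 rose and 23 fell (25 and 23 adjusted over the list alone): Spaca3 rose 2.06-fold, while Tssk6 fell from 365 to 219 CPM and Smcp from 659 to 402 CPM. The Sertoli, peritubular and macrophage counts were unchanged when adjusted over the list alone. None of the Sertoli, peritubular, macrophage and spermatid lists passed camera (adjusted p of 0.968, 0.190, 0.426 and 0.614). Under fry the peritubular, macrophage and spermatid lists passed as higher (adjusted p of 0.0127, 0.0369 and 0.0369) and the Sertoli list did not (0.839). Of the erythroid markers 2 could be tested, and neither Hbb-bs nor Alas2 passed (adjusted p of 0.094 and 0.446 by edgeR). Hbb-bs passed as higher in limma on log2 TPM (adjusted p of 0.0129) and with the effective length offset (0.027), and Alas2 as lower without KK replicate 1 (0.0144).

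Immediate early genes, which respond within minutes to dissociation and other stimuli, were higher, with 15 of 29 risen and 0 fallen (17 risen adjusted over the list alone). Nr4a3 rose from 0.518 to 2.58 CPM (7.41-fold without WT replicate 2), and the list passed camera with an adjusted p of 8.0e-05 but not with an estimated correlation (adjusted p = 0.269). Of 76 axonemal and ciliary genes 40 fell and 17 rose (42 and 18 adjusted over the list alone), and their median of -0.11 lay within the range of autosomal lists of like abundance (-0.16 to -0.04). Dnah8, an axonemal dynein heavy chain gene, fell from 2044 ± 103 to 1333 ± 31.1 CPM, while Ropn1 rose from 90.9 to 137 CPM. Of 56 translation factor genes 21 fell and 8 rose, among them Eif5, which fell from 857 to 588 CPM, and of 303 zinc finger genes of the Zfp series 89 fell and 36 rose, counts that did not change when adjusted over the list alone. The camera adjusted p was 0.0026, 0.037 and 0.032 for these 3 lists, and with an estimated correlation the adjusted p = 0.360, the adjusted p = 0.281 and the adjusted p = 0.360. For translation factors the median (-0.06) and the mean (0.01) differed in sign. The translation factor list did not pass with a mean CPM of at least 1 (adjusted p of 0.095) or TMM factors from autosomal genes (0.059), nor the zinc finger list without KK replicate 1 (0.090). With a length trend offset the axonemal and zinc finger lists no longer passed (adjusted p of 0.058 and 0.190).

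Of 80 ribosomal protein genes 30 rose, 1 fell and 49 did not pass (29 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.09. Rpl10a rose from 80.6 to 235 CPM (2.92-fold) and stood apart from the list. The camera adjusted p of 4.4e-04 was lost with an estimated correlation (adjusted p = 0.698), under fry (adjusted p of 0.103) and with a length trend offset (adjusted p of 0.980, direction turned). Nuclear genes of oxidative phosphorylation (17 of 78 risen, 6 fallen), the heat shock (4 and 8 of 21), unfolded protein (8 and 6 of 30), p53 and apoptosis (6 and 4 of 25), transposon silencing (7 and 11 of 28), interferon (6 and 3 of 17) and replication histone lists (4 and 2 of 19) did not pass camera, though the oxidative phosphorylation list did without KK replicate 2 (adjusted p of 0.028). Fry called the heat shock list lower (adjusted p of 0.048) and the unfolded protein list higher (0.045). Adjusted over the list alone, 15 oxidative phosphorylation, 10 transposon silencing and 3 histone genes rose, and the other counts of these lists were unchanged. Morc1, a transposon silencing gene, rose from 6.24 to 21.9 CPM, Hspe1 rose from 2.70 to 6.96 CPM and Cxcl10 rose 6.26-fold from 0.498 CPM. Median and mean differed in sign for the p53, transposon silencing and histone lists, and the heat shock list had a median and mean above 0 with a downward test. Of the lists tested, the medians of the X-linked, Y-linked, Leydig, spermatogonial, peritubular, immediate early, spermatid, ribosomal protein and oxidative phosphorylation lists lay above the range of autosomal lists matched on CPM, those of the RNA decay, zinc finger and Sertoli lists lay below it, and the other medians lay within it.

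**Figure D4:**
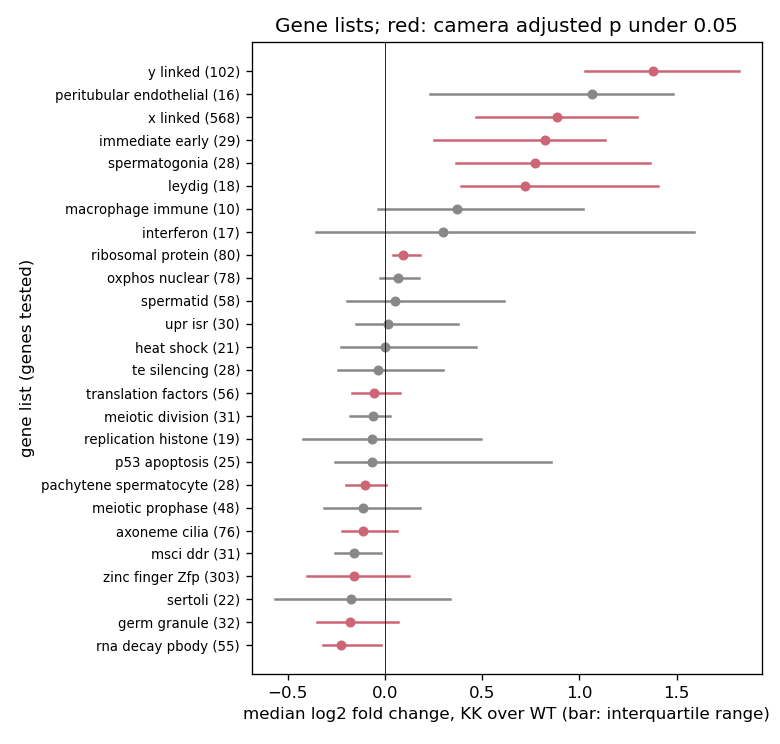
Median log2 fold change of KK over WT (horizontal axis) of each tested gene list (vertical axis, number of genes tested in brackets); bars give the interquartile range and red marks a camera adjusted p under 0.05 with a preset correlation. The sex chromosome lists have medians of 0.89 and 1.38, and the germ granule list a median of -0.18.

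Isoform usage could not be compared with the reliability of the gene levels. The planned test, edgeR's diffSpliceDGE with a likelihood-ratio fit, called 571 of 8119 genes, but this number does not measure how many genes differed. On simulated counts with the dispersion of these isoforms, 83.2% of its calls were unchanged genes. When the 4 libraries were regrouped so that each group held 1 WT and 1 KK library, it still called 278 and 328 genes. The other test, limma's diffSplice, called 334 genes, against 1 and 2 in the regrouped libraries. Regrouping puts the genotype difference into the spread within groups, which favours few calls, so it does not show how many of the 334 were false. On simulated counts limma recovered 10.3% of the genes changed 2-fold, and 20.5% of its calls were unchanged genes. Both tests called 142 genes. Of the 5 genes with the smallest p in the edgeR test, Ipp alone passed in limma (adjusted p of 0.010). Its isoform Ipp-202 held 99.99% of the gene's transcripts in WT and 0% in KK, where Ipp-201 held 100%. Aspscr1, Slc9a8, Tcp11 and Slc2a3 did not pass in limma (adjusted p of 0.067, 0.070, 0.401 and 0.642). All 5 passed in the quasi-likelihood fit added later (adjusted p from 5.4e-08 to 0.0034), although 78.2% of that fit's calls on simulated counts were unchanged genes. In each of these 5 genes an isoform had no counts in both libraries of one genotype, such as an isoform of Slc9a8 with 438 and 444 counts in WT and 0 in KK, and the error of assigning reads among isoforms was not analysed here. For Ddx4 the share of Ddx4-202 was 77.4% in WT and 70.9% in KK, with an adjusted p of 0.059 in edgeR's likelihood-ratio fit, 0.846 in its quasi-likelihood fit and 0.044 in limma.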

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

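The GC trend offset, the TMM factors from autosomal genes, the trend offsets applied to lists and the quasi-likelihood isoform fit were chosen after seeing the data. Ddx4 stayed lower under every alternative run (log2 fold change -2.38 without KK replicate 1 to -2.25 with library size only). The count of changed genes was 5925 to 6552 with one library left out, where the lone sample is assumed to vary like the other group. DESeq2 gave 4564 genes, 2037 higher, with 803 rises and 38 falls of at least 2-fold, and 193 X-linked and 29 Y-linked rises. Limma on log2 TPM gave 3408 (1923 higher, 1485 lower), 596 and 30 at 2-fold, 176 X-linked and 43 Y-linked. The effective length offset gave 4662 (2379 higher, 2283 lower) and 45 Y-linked. Falls of at least 2-fold numbered 76 with library size only and 78 with a mean CPM of at least 1. The cause of these differences was not tested. The replicate numbers of the labels are not said to pair samples, and the correlation of deviations was -0.06; with a replicate block 7309 genes passed.

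With an estimated correlation 0 lists passed, 0 higher and 0 lower (adjusted p = 0.269 for germ granule, 0.147 for X-linked and 0.147 for Y-linked genes). On simulated counts this test called a list shifted by 0.4 (log2) in 6 of 10 data sets. The other simulated genes were unchanged and independent, unlike here, so this rate does not measure its power in these data. The estimated correlation was 0.059 for germ granule genes, above the preset 0.01. For X-linked and Y-linked genes it lay below the preset, so correlation cannot account for the calls lost there. Fry called 18 lists, among them 7 that camera had not called: meiotic division (0.0127), peritubular (0.0127), macrophage, spermatid and sex chromosome silencing (0.0369 each), unfolded protein (0.045) and heat shock (0.048). Directions turned for lists that had not passed: under fry Sertoli (0.839) and p53 (0.587), and with the length trend offset spermatid (0.357), p53 (0.958), transposon silencing (0.958) and oxidative phosphorylation (0.274). The ribosomal protein list, which had passed, also turned (0.980). With one library left out the adjusted p ran from 0.844 to 0.979 for p53 (turned without WT replicate 1, WT replicate 2 or KK replicate 2), from 0.776 to 0.946 for replication histones (turned without KK replicate 1) and from 0.563 to 0.978 for meiotic prophase (turned without KK replicate 2). Oxidative phosphorylation, which had not passed, did so without KK replicate 2 (0.028). Isoform calls were 253 at 30 counts, 334 in limma, 183 with the quasi-likelihood fit, 435 with a replicate block and 376 to 626 with one library left out, the lowest without KK replicate 2. Of 114 named genes besides Ddx4, 72 kept their call and direction under every alternative that gave a value (59 of 84 genes with all 16 alternatives and 13 of 30 with fewer), and 40 lost the call in at least one. Fancm went from a log2 fold change of -0.51 to 0.00297 in limma on log2 TPM, where it did not pass (adjusted p of 0.995). Alas2, which had not passed, had log2 fold changes from -1.61 to 0.19 with one library left out.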

Other observations

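The length trend offset for single genes and the camera test with an estimated correlation were set before the data were examined; the other tests in this part, and the bounds by which each explanation was judged, were chosen after the results were seen. The genes named here that the report does not name were chosen after their values were seen. The secreted-protein genes Lcn2 and Apoe rose in KK: Lcn2 went from 14.9 ± 0.27 to 106 ± 0.40 CPM (7.13-fold) and Apoe from 10.3 to 31.3 CPM. Stra8, a gene of meiotic entry, rose from 2.36 to 6.35 CPM and Ube2c from 19.8 to 54.1 CPM. Setd1b, which like Kmt2d encodes a histone H3 lysine methyltransferase, fell from 58.3 to 27.1 CPM. Autosomal genes with a mean of at most 1 CPM had a median log2 fold change of 0.37, and those above 100 CPM one of -0.09. Transcripts over 5000 bases had a median of -0.18 and those up to 1000 bases one of 0.11. The nuclear rRNA gene CT010467.1 took 2967 ± 1033 CPM in WT and 1397 ± 455 in KK (adjusted p of 2.0e-07 by edgeR).

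X-linked genes were higher in KK, with a median log2 fold change of 0.89. The general rise of low-abundance genes is argued against as the whole cause, since only the top 2.5% of 10000 autosomal lists matched on CPM had a median above 0.226. More protamine-expressing spermatids are argued against by the summed CPM of Prm1, Prm2, Tnp1 and Tnp2, whose log2 ratio was -0.184. These genes went both ways (log2 fold changes from -0.53 for Prm2 to 0.39 for Tnp1), but each lay below the X median by more than 2 SE. Their sum was high in both genotypes, 3065 CPM in WT and 2697 CPM in KK, so the libraries may not hold spermatocytes alone. The spermatid list median of 0.05 lay above its matched range (-0.16 to -0.03), though below the X median. More somatic cells are argued against for the germline-restricted X-linked genes, whose median was 0.794 (20 of 26 rose, although Akap4 fell), whereas more spermatogonia or early germ cells, in which the X chromosome is not silenced, remain a candidate explanation, because the spermatogonia list had a median of 0.772, though from low levels such as 1.48 CPM for Zbtb16 in KK. Early round spermatids, a mixture of several cell types and weaker silencing of the sex chromosomes in the mutant remain open as untested hypotheses.

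Rises of at least 2-fold outnumbered falls. To judge genomic DNA in the KK libraries, low-abundance autosomal genes were set against olfactory and vomeronasal receptor genes. The autosomal genes gained a median of 0.0766 and a mean of 0.128 CPM per kb, the receptor genes a mean of 0.00475. The receptor genes took 0.0062% of the counts in WT and 0.0081% in KK. Only the autosomal genes had passed the expression filter on these same libraries, so the sets are unlike and genomic DNA stays open. A transcript length trend is argued against because rises made up 91.8% of such calls with the length trend offset. Cells of other types, whose Leydig and spermatogonial markers rose, may contribute, and an effect of the genotype within spermatocytes stays open.

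Germ granule genes were lower in KK by camera with a preset correlation, with and without Ddx4 (adjusted p of 2.4e-07 and 0.00108), but not with an estimated correlation (adjusted p = 0.269 and adjusted p = 0.36), so the pattern is a hypothesis. For the list with Ddx4, a length trend as the whole cause is argued against by the preset-correlation camera call with the length trend offset (adjusted p of 2.6e-06). No estimated correlation was run with this offset. Ddx4 was not left out with this offset either, so for the other members a length trend stays open. A lower share of spermatocytes with an even gain of all other cell types, which would raise their markers alike, is argued against, under the bound kept. The Leydig, spermatogonial and peritubular medians lay 0.896, 0.947 and 1.24 above the Sertoli median. A permutation test over genes, which are not independent, gave adjusted p of 0.0017, 0.00012 and 0.00277. A lower share with an uneven gain, as of Leydig cells and spermatogonia but not Sertoli cells, could give the same values and stays open. The interquartile ranges of the Leydig and spermatogonial lists lay above that of Sertoli (-0.566 to 0.335), while those of the peritubular (0.232 to 1.48) and macrophage lists overlapped it, and the macrophage difference of 0.548 did not pass (adjusted p of 0.109); that bound, Sertoli lying apart from at least 1 list, was the last of 3 versions set after the values were seen, and a version asking it to lie apart from all 4 lists left the explanation open. The general fall of abundant genes remains a candidate explanation, because the list median of -0.18 did not reach the lowest 2.5% of medians of matched autosomal lists, which began at -0.193, and a difference in the stage of the spermatocytes collected was not tested.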
